A study of Mus musculus with 3 samples.

How the data were processed

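The study measured RNA from pools of mouse blastocysts, 1 library for each of 3 states (dormant, reactivating 6 h after E2 and reactivated 12 h after E2), by sequencing rRNA-depleted total RNA on the SOLiD platform with 50 bp single-end reads, per the labels' protocols. For each library the authors deposited a table of 31510 genes with read counts, per the file headers split into reads in exons, in introns, across exon junctions and on the opposite strand of the gene. The same tables hold an RPKM per gene that the authors computed, per the file headers, that is, exon reads scaled to the exon length of the gene and to the total reads of the library. The submitters' processing notes name the genome build GRCm38. The aligner, the counting tool and the annotation release are not given in the sources used here.

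The deposited RPKM was compared with the deposited counts. For genes with at least 200 reads, exon reads divided by exon length and by RPKM gave totals of 14118723, 15687239 and 18982195 reads in the dormant, reactivating and reactivated libraries. With those totals each RPKM followed from its own reads within 2% or 0.011 RPKM, with 1 exception among the 31510 genes of the 3 tables, Rlim in the reactivated library, which is given with both values. Gene symbols, coordinates, biotypes and GC content came from GENCODE M21 (GRCm38) by Ensembl ID. It held 26687 of the IDs (84.7%), with the same chromosome for 99.7% of them and the same gene length for 29.6%, so that the annotation differed from the authors' in gene models. Coordinates are those of M21, and exon lengths those of the deposited tables. Arl14 has no coordinates in M21 under its ID, and its chromosome is that of the deposited tables.

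Differences were computed as log2((RPKM + 1)/(RPKM + 1)), a scale on which the pseudocount of 1 understates changes of low genes. With 1 library per state there was no test across replicates, no SD and no p-value. A gene counted as higher or lower by a rule fixed before the data were examined: a log2 difference of at least 1 in size (2 times) and at least 1 RPKM in the higher of the 2 libraries. Each count has an exact 95% Poisson interval, and ratios of counts have exact binomial intervals. Shares of reads have Wilson intervals. All of these cover counting error only, and reads without molecular identifiers are not independent molecules. The planned rule named CPM and 20 reads for files of raw counts and the authors' normalised value otherwise. Since the tables hold both, RPKM served as the reported value and CPM over the gene total, with at least 1 CPM and 20 reads, as an alternative chosen after the data were seen.

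Gene lists, 45 in number, were written before the data were examined, and 44 of them had members with at least 1 RPKM in a library. For each, the median log2 difference of its measured members was placed among the medians of 10000 random lists of the same size, drawn with replacement within 20 bins of mean expression from the 12454 genes with at least 1 RPKM in a library. A list stood apart when it lay outside the middle 95% of the random lists. About 2.2 of 44 lists would do so by chance if their members varied as independently as randomly drawn genes. Members that vary together between libraries would raise that number, and without replicates its size is unknown. These percentiles describe the 3 libraries and are not p-values. X-linked genes were treated in the same way, with autosomal sets as the background. For sets matched on expression, exon length and GC content together, the number of bins was set to 5. The 3 comparisons share libraries, so that they are not independent of each other.

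Named genes followed a rule fixed before the data were examined. It took the 12 genes with the largest rise and the 12 with the largest fall per comparison among changed genes with at least 5 RPKM and a symbol that is not a predicted gene, small RNA or pseudogene, and the 3 members of each list with the largest change at 5 RPKM or more. It also took 37 genes fixed by name, of which 35 were in the tables, and gave 302 genes. Other members of the lists are named where they passed the size rule, chosen after their values were seen.

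Tests on simulated counts with the real libraries' means and totals came before the real analysis. Counts were simulated for all 31510 genes, and changes were placed in protein-coding genes with at least 3 RPKM in the pooled pair of libraries. Recovery of lower genes was not covered. Of 50 genes raised 3 times, 50 were recovered in each comparison. Of 50 lowered to 0.333 of their level, 47 were recovered for reactivating with dormant, 47 for reactivated with dormant and 49 for reactivated with reactivating. Of 50 genes changed 1.5 times upwards none was recovered, as the rule asks for 2 times. The list test instead drew 200 lists of 30 genes at random from the 12454 genes with at least 1 RPKM in a library. It used the real log2 differences of reactivated against dormant. Of these lists 10 fell outside the middle 95%, a share that random drawing itself sets, and of 200 lists raised by 0.5 on the log2 scale 192 were called. Counting error alone was simulated in 20 pairs of unchanged libraries per comparison.

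The alternatives fixed in advance were a pseudocount of 0.1, no minimum or a minimum of 5 RPKM, median-ratio scaling, upper-quartile scaling, a total without mitochondrial, small RNA and histone genes, counting intervals that do not overlap, random lists without matching, an X set without predicted genes, and minimums of 0.1 and 5 RPKM for detected genes. Added after the data were seen were CPM, matching on exon length or GC content, counts and backgrounds of protein-coding genes or of genes outside the small RNA classes, and intron reads for the X chromosome. For introns, genes that host no annotated small RNA and had at least 50 intron reads were used. After a first round of results, the value tracked for each list was changed from its median to its percentile and the comparison of chromosomes and of Y-linked genes was added, with the rules above unchanged. Reads on the opposite strand were used only to describe the libraries. Genes with near-identical copies (histones, ribosomal proteins, Ldha, Pgk1, Myl12b) are uncertain, as the treatment of reads with several matches is not given in the sources used here. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.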

Results

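RNA from mouse blastocysts was sequenced in 3 states of delayed implantation, the condition in which an embryo stops growing inside the uterus until the mother's ovarian hormones return. CD-1 mothers, 2 months old, lost their ovaries on day 4 of pregnancy and received 2 mg of progesterone per mouse on days 5 to 7. Dormant blastocysts were flushed out on day 8. Estradiol (E2), the hormone that ends the delay, was given on day 7 to the other mothers, whose blastocysts were collected 6 h later (reactivating) or 12 h later (reactivated). Each state was 1 library made from more than 3000 pooled blastocysts, so that differences between states had no replicate check, and the time and day of collection changed together with the state. Ribosomal RNA was depleted from total RNA, and 50 bp single-end SOLiD reads were counted per gene. The libraries held 9298675 reads in exons in the dormant state, 10364607 in the reactivating state and 12941447 in the reactivated state. Introns held a further 3554921, 3479754 and 3982790 reads in the same order.

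The libraries were close in the number of genes they detected and differed in which RNA classes took the reads. At least 1 RPKM was reached by 11497 genes in dormant, 11535 in reactivating and 11089 in reactivated blastocysts. The mitochondrial ribosomal RNA mt-Rnr2 took 17.8% of exon reads in dormant blastocysts (95% Wilson interval 17.8 to 17.8%), 18.6% in reactivating and 24.3% in reactivated ones. Nuclear small RNA genes took 16.8%, 13.7% and 14.0%. Histone genes took 0.0695% of exon reads (interval 0.0678 to 0.0712%) in dormant, 0.104% (0.102 to 0.106%) in reactivating and 0.0948% (0.0932 to 0.0965%) in reactivated blastocysts. Cytosolic ribosomal protein genes took 0.530%, 0.660% and 0.427%. The 10 highest genes held 35.3%, 32.0% and 34.4% of the summed RPKM. With 3 reads as the limit of what a count of 0 allows, a gene with 1 kb of exon could hide up to 0.212 RPKM in the dormant library and 0.158 RPKM in the reactivated one. All intervals cover counting error only.

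The first comparison asked what had changed in the blastocyst 6 h after E2. Few protein-coding genes had moved, 68 higher and 29 lower among 9960, and those that had were mostly short. Myl12b, a myosin light chain gene (ENSMUSG00000034868, GRCm38 chromosome 17, 70973133 to 70990890), rose from 56.5 RPKM (95% Poisson interval 52.3 to 60.8) to 427 RPKM (416 to 438). Sec31b, a gene of the vesicle coat that carries proteins out of the endoplasmic reticulum (ENSMUSG00000051984, chromosome 19, 44516957 to 44545864), rose from 2.35 RPKM (1.95 to 2.81) to 20.5 (19.3 to 21.7), and Wdr89 from 33.5 to 126 RPKM. Scand1 fell from 28.3 RPKM (24.8 to 32.2) to 10.8 (8.73 to 13.1), and Mrpl57, a protein of the mitochondrial ribosome, from 16.3 to 4.66 RPKM. Snrpf and Snrpd1, core proteins of the spliceosome, rose from 1.65 to 6.99 RPKM and from 3.78 to 12.98 RPKM.

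Of the fixed gene lists, replication-dependent histones and apoptosis genes stood above matched random lists at 6 h, and mitochondrially encoded proteins, immediate early genes, Wnt signalling and the mTOR, PI3K and growth list stood below. Of 48 measured histone genes, 6 rose and 5 fell. Hist1h2bg rose by 2.31 on the log2 scale, from 17.0 to 87.8 RPKM, and Hist1h4n by 1.98, while Hist1h2ab fell by 1.44 and Hist1h4c fell by 1.15. The list median was 0.19 (percentile 99.0 of random lists), and the list lost its place with random lists matched on exon length (percentile 92.0), with CPM in place of RPKM (94.3) and at a minimum of 5 RPKM (97.1). None of the 13 mitochondrially encoded protein genes passed the size rule, but their median was -0.31 (percentile 0.50). None of the 22 apoptosis genes, 23 immediate early genes, 22 Wnt genes or 32 mTOR and growth genes passed either, with medians of 0.26, -0.08, -0.11 and -0.07. Without matching, the immediate early genes were at percentile 3.52, and at a minimum of 5 RPKM the apoptosis list was at 84.6 and the mTOR list at 7.42. Of 44 lists these 6 stood apart, against about 2.2 by chance for lists of independent genes. Of the 6, 2 kept their place in all 10 alternatives, the mitochondrially encoded proteins and Wnt signalling. Cell cycle, glycolysis, cholesterol and chaperone genes, which moved by 12 h, lay within the random range, with 0 of 20 glycolysis genes and 0 of 40 G1/S genes passing.

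By the size rule, a log2 difference of at least 1 on RPKM + 1 with at least 1 RPKM in the higher library, 325 genes were higher and 372 lower at 6 h among 12126 tested. Counting error alone gave on average 54.5 higher and 52.95 lower in simulated pairs of unchanged libraries. The changed genes had a median exon length of 156 bases, and 93.7% of them were under 1 kb, against 22.0% of the tested genes. Small RNA genes made up 127 of the higher and 254 of the lower genes. In all, 183 higher and 198 lower genes had intervals that did not overlap between the libraries. Of the changed protein-coding genes 70.1% were higher, a share that became 57.9% with upper-quartile scaling and 59.8% with median-ratio scaling. With CPM and at least 20 reads, 180 protein-coding genes were higher and 80 lower, and 49.8% of all changed genes were under 1 kb, against 14.1% of those tested. Hist1h2bg, Hist1h4n and Myl12b have near-identical copies elsewhere in the genome, so that their values are uncertain.

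**Figure D1:**
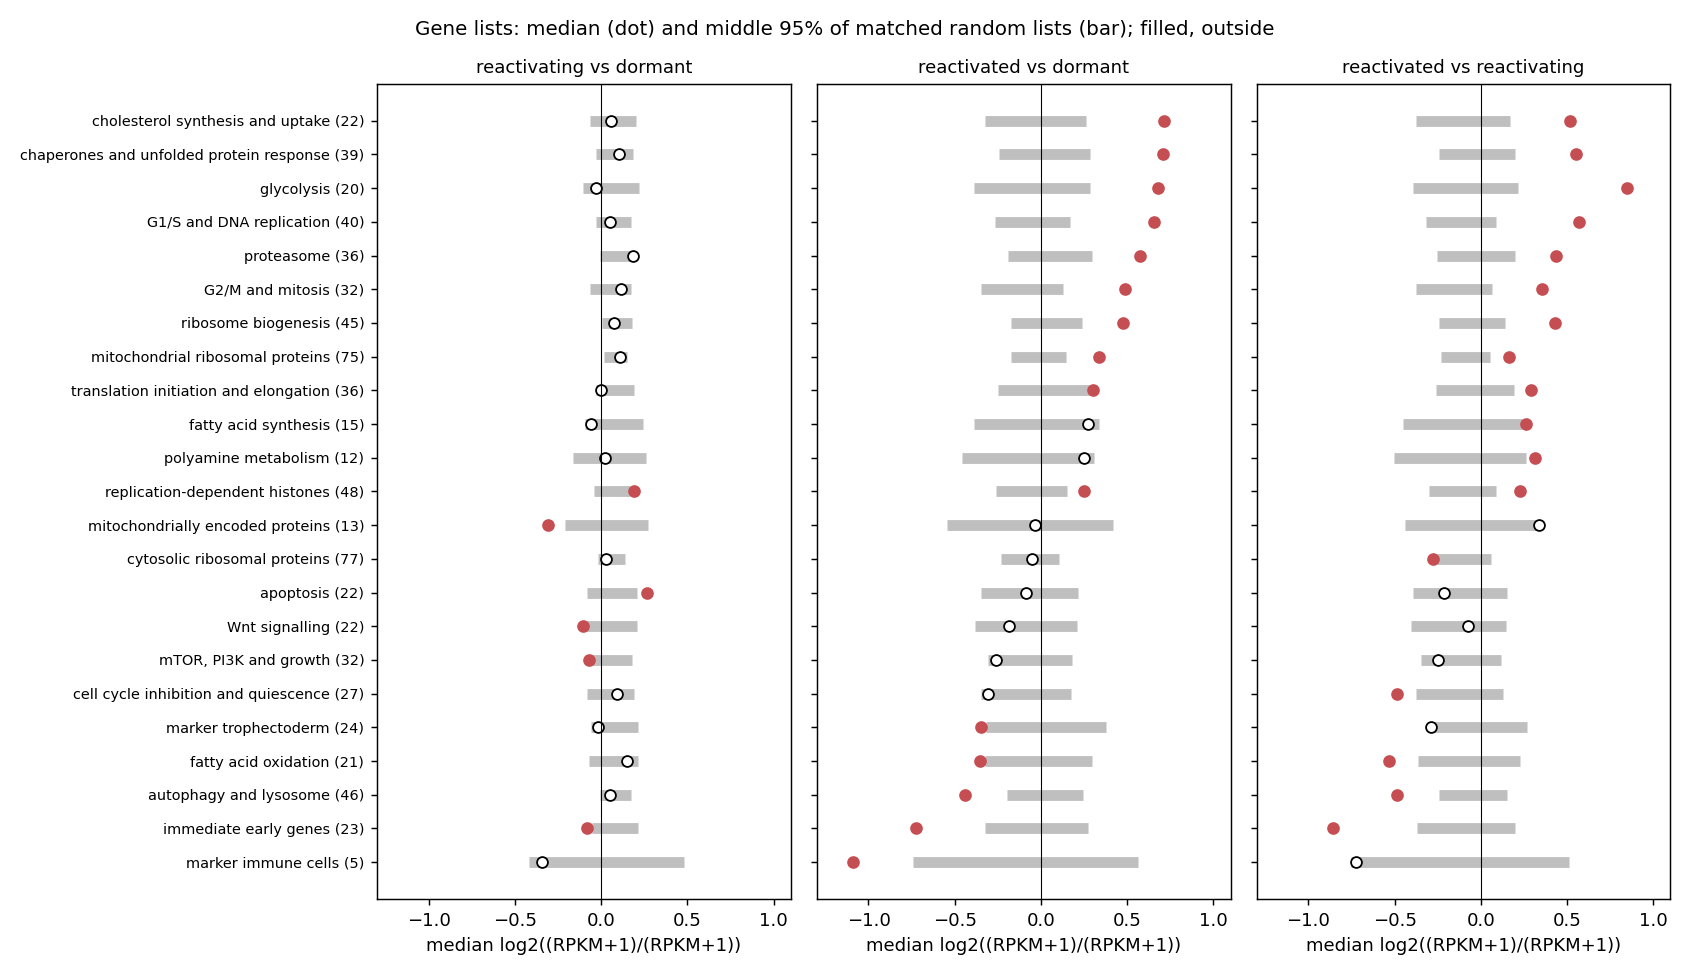
Median log2 difference of each gene list that stood apart in at least 1 comparison (dots, number of measured genes in brackets) and the middle 95% of 10000 random lists matched on expression (grey bars), in the 3 comparisons of the 3 libraries. Filled dots lie outside the bar; at 12 h against dormant, cholesterol genes (0.71) and chaperones (0.71) lie highest and immune cell markers (-1.09) and immediate early genes (-0.72) lowest.

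The second comparison, reactivated against dormant, asked what distinguished blastocysts 12 h after E2 from dormant ones. As lists, genes of glycolysis, cholesterol synthesis, the cell cycle, protein folding and ribosome production stood above random lists. Immediate early genes and genes of autophagy and lysosomes stood below them. Among the named genes the greatest rise was in Prap1, a secreted protein of epithelia (ENSMUSG00000025467, chromosome 7, 140093395 to 140097200), at 0.70 RPKM (0.257 to 1.52, 6 reads) in dormant and 35.4 RPKM (32.0 to 39.0, 408 reads) in reactivated blastocysts. Whether its RNA came from the embryo or from maternal uterine epithelium was not tested. Slc40a1, the iron exporter ferroportin (ENSMUSG00000025993, chromosome 1, 45908068 to 45926523), rose from 6.33 to 69.7 RPKM. Krt19, a keratin of the trophectoderm (ENSMUSG00000020911, chromosome 11, 100140810 to 100148665), rose from 16.03 RPKM (14.3 to 17.9) to 123 (119 to 127), and the placental gene Plac1 from 3.02 to 24.2 RPKM. The glutamate transporter Slc1a1 rose from 24.0 to 135 RPKM and the zinc transporter Slc30a1 from 4.97 to 36.8 RPKM.

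On the scale of RPKM + 1 the greatest fall among the named genes was in Gjb2, a gap junction protein (ENSMUSG00000046352, chromosome 14, 57098600 to 57104702), from 190.1 RPKM (186 to 195) to 13.2 (12.2 to 14.3). Arl14, a small GTPase gene on chromosome 3, fell from 26.4 to 1.18 RPKM, which as a plain ratio of dormant to reactivated (22.4) was more than that of Gjb2 (14.4). Adh1, an alcohol dehydrogenase that oxidises retinol (ENSMUSG00000074207, chromosome 3, 138260991 to 138290698), fell from 1375 RPKM (1358 to 1392) to 237 (231 to 243). Nupr1, a stress-induced chromatin protein, fell from 104 to 14.0 RPKM, and Gpnmb from 22.4 to 1.76 RPKM.

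Of 20 measured genes of glycolysis and lactate transport 7 rose and none fell (median 0.68, percentile 100). The lactate exporter Slc16a3 went from 0.690 RPKM (0.438 to 1.04) to 13.4 (12.4 to 14.5), the pyruvate kinase Pkm from 18.5 to 72.4 and the lactate dehydrogenase Ldha from 3.55 to 24.6. Of 22 cholesterol genes, 7 rose and none fell (median 0.71, percentile 100), among them Msmo1 from 17.6 to 42.6 RPKM. Of 21 genes of fatty acid oxidation none rose and 2 fell, Cpt1a, which brings fatty acids into mitochondria, from 10.8 to 3.99 RPKM and Acadl from 35.9 to 16.9. That list's median of -0.36 stood at percentile 1.74, but at 3.39 with CPM, at 4.20 without matching and at 3.01 with matching on GC content, and Acadl was at -0.99 with median-ratio scaling. Ldha and Pgk1 (0.540 and 4.72 RPKM) have many pseudogenes, so that their values are uncertain.

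Of 40 genes of G1/S and DNA replication, 9 rose and none fell (median 0.65, percentile 100). Cyclin E led them, with Ccne1 (ENSMUSG00000002068, chromosome 7, 38097984 to 38107534) going from 2.59 RPKM (2.02 to 3.27) to 17.5 (16.2 to 18.9) and Ccne2 from 2.07 to 11.8, followed by the replication factors Cdc45 (3.12 to 13.2) and Cdc6 (1.40 to 6.04). Of 32 genes of G2/M and mitosis, 6 rose, such as Cdk1 from 11.5 to 28.6 RPKM, and Cdc25b fell (median 0.48, percentile 100). Of 27 genes of cell cycle inhibition and quiescence, 5 fell. The CDK inhibitor Cdkn1a fell from 15.2 RPKM (13.8 to 16.6) to 3.27 (2.75 to 3.86), Foxo3 from 16.2 to 4.73, and Btg1, Btg2 and Mxd4 fell too, while Ccng2, an atypical cyclin of arrested cells, rose from 1.82 to 13.2. The median of that list, -0.31, lay within the random range (percentile 4.66), and below it with a pseudocount of 0.1 (0.710), with CPM (0.825) and at a minimum of 5 RPKM (1.61). Histones were higher as a list (14 rose, 5 fell, 29 neither, median 0.25, percentile 99.7), although at percentile 95.3 at a minimum of 5 RPKM.

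Genes of protein folding, breakdown and production stood higher. Of 39 chaperones and unfolded protein response genes, 13 rose (median 0.71, percentile 100), led by Hsph1 (20.2 to 94.1 RPKM), Hsp90aa1 (9.67 to 29.5) and Hspa5, the main chaperone of the endoplasmic reticulum (121 to 266). Ddit3, a transcription factor of prolonged endoplasmic reticulum stress that the same list holds, fell from 24.4 to 8.79 RPKM. Of 36 proteasome genes 6 rose and none fell (median 0.58, percentile 100), with Psmc3 at 49.8 and 156 RPKM. Ribosome biogenesis had a median of 0.47 (2 of 45 rose, among them Ddx21 from 42.4 to 96.2 RPKM) and mitochondrial ribosomal proteins of 0.34 (2 of 75 rose), both above the random lists. Translation factors had a median of 0.30 at percentile 98.1, with 1 of 36 rising and 1 falling, and lost this place under 4 of the 10 alternatives (96.8 to 97.3). The 77 cytosolic ribosomal protein genes had a median of -0.05, within the random range.

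Immediate early genes, which growth factors and stress switch on within minutes, were lower as a list (9 of 23 fell, none rose, median -0.72, percentile 0.0). Rhob fell from 97.9 RPKM (91.3 to 105) to 16.7 (14.4 to 19.2), Junb from 47.2 to 12.5, Jund from 74.0 to 22.0 and Fos from 49.8 to 17.6. Of 46 genes of autophagy and lysosomes 9 fell and none rose (median -0.44, percentile 0.0). They included Tfeb, the transcription factor that controls lysosome production, from 31.0 to 7.74 RPKM, the autophagy kinase Ulk1 from 13.1 to 3.03 and the autophagosome protein Map1lc3b from 18.1 to 4.70.

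Lineage markers moved in both directions. Of 24 trophectoderm markers, Krt19, Tinagl1 and Elf5 rose and Cdx2, Gata3 and Dab2 fell. Cdx2, a regulator of trophectoderm identity (ENSMUSG00000029646, chromosome 5, 147300805 to 147307270), fell from 113 RPKM (109 to 116) to 34.8 (33.0 to 36.7), Tinagl1 rose from 76.7 to 249 and Elf5 from 30.1 to 81.3. The trophectoderm median of -0.35 stood at percentile 1.80, but at 3.41 without matching and at 2.64 with matching on GC content. Of 28 entries of the naive epiblast list (27 genes, with Tet1 in the tables under 2 IDs) none rose and 6 fell, among them Tet2 (25.2 to 7.82 RPKM), Stat3 (35.8 to 12.7) and Klf2 (7.45 to 2.12), with the list median of -0.26 within the random range (percentile 7.72). Its core factors did not pass the rule: Pou5f1 was at 87.1, 125 and 124 RPKM in the 3 states, Nanog at 14.6, 21.7 and 17.7 and Sox2 at 13.95, 16.4 and 13.5. At a minimum of 5 RPKM the epiblast list fell to percentile 0.0. Apoe, Rspo3 and Ttr fell among the 22 primitive endoderm markers, whose median of -0.15 lay within the random range.

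Inflammatory genes went both ways. Of 20 measured genes of the inflammatory list, Saa3, S100a8 and S100a9 rose and Il6 and Il1rn fell. Saa3, an acute phase protein (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), was at 2.67 RPKM (1.63 to 4.13) in dormant, 5.29 (3.85 to 7.10) in reactivating and 47.3 (43.2 to 51.8) in reactivated blastocysts. S100a8 (chromosome 3, 90668978 to 90670035), a calcium-binding protein abundant in neutrophils, was at 4.21 (2.67 to 6.32), 2.47 and 16.6 RPKM (13.8 to 19.8), and its partner S100a9 at 5.43, 3.91 and 20.4. Il6 fell from 19.5 RPKM (17.4 to 21.8) to 6.10 (5.09 to 7.26). Tnf had 3, 16 and 1 reads in the 3 libraries, too few for a level. The list's median of -0.20 and mean of 0.12 differed in sign and lay within the random range (percentile 28.0), and at a minimum of 5 RPKM the median turned to 0.78 at percentile 99.99. Markers of immune cells moved the other way, since 3 of 5 measured ones, Laptm5, Cd14 and Tyrobp, fell (median -1.09, percentile 0.240). That median is the value of Tyrobp, which had 9 reads in dormant and 0 in reactivated blastocysts, too few for a level. Of 7 measured markers of uterine epithelium, Lif and Wfdc2 fell and none rose, of 3 measured stromal markers none passed, and no marker of red blood cells reached 1 RPKM. The 13 interferon response genes held 3 that fell, Bst2, Irf9 and Isg15, and a median of -0.24 within the random range.

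Among genes of signalling between embryo and uterus, the ErbB receptors Erbb3 (38.7 to 7.86 RPKM) and Erbb2 (21.95 to 6.56) fell, while the ligand Hbegf stood at 5.70 RPKM (4.91 to 6.57) in dormant and 10.9 (9.98 to 11.95) in reactivated blastocysts, a log2 difference of 0.83 that did not pass. The ErbB list held 8 measured genes, and its median (0.18) and mean (-0.20) differed in sign. Odc1, the rate-limiting enzyme of polyamine synthesis, rose from 6.49 RPKM (5.59 to 7.49) to 15.3 (14.1 to 16.6), while Arg1 fell from 4.73 to 0.330. Of 22 Wnt genes Wnt3a (15.2 to 2.21 RPKM), Wnt6 (26.1 to 7.03), Wnt9a and Axin2 fell. Itga7 and the tight junction protein Ocln (24.3 to 70.8) rose among 40 genes of adhesion and matrix, where Fn1 and Lama5 fell. The medians of the Wnt (-0.18), polyamine (0.25) and adhesion (0.08) lists lay within the random range. Ptgs1, Ptgs2, Erbb4, Esr1 and Cnr1 stayed under 0.5 RPKM in each library.

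The rule counted 634 genes higher and 922 lower among 12037 tested, of which 515 and 788 had intervals that did not overlap, and 361 higher and 550 lower among protein-coding genes. With CPM over the gene total the counts were 639 and 1388, and counting error alone gave on average 50.9 and 51.1. Of 44 lists with measured members, 10 stood above and 5 below the random lists, against about 2.2 by chance for lists of independent genes. Of these 15, 11 kept their place in all 10 alternatives. Among autosomal protein-coding genes, the median log2 difference went from 0.16 in the fifth with the lowest GC content to -0.30 in the fifth with the highest.

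**Figure D2:**
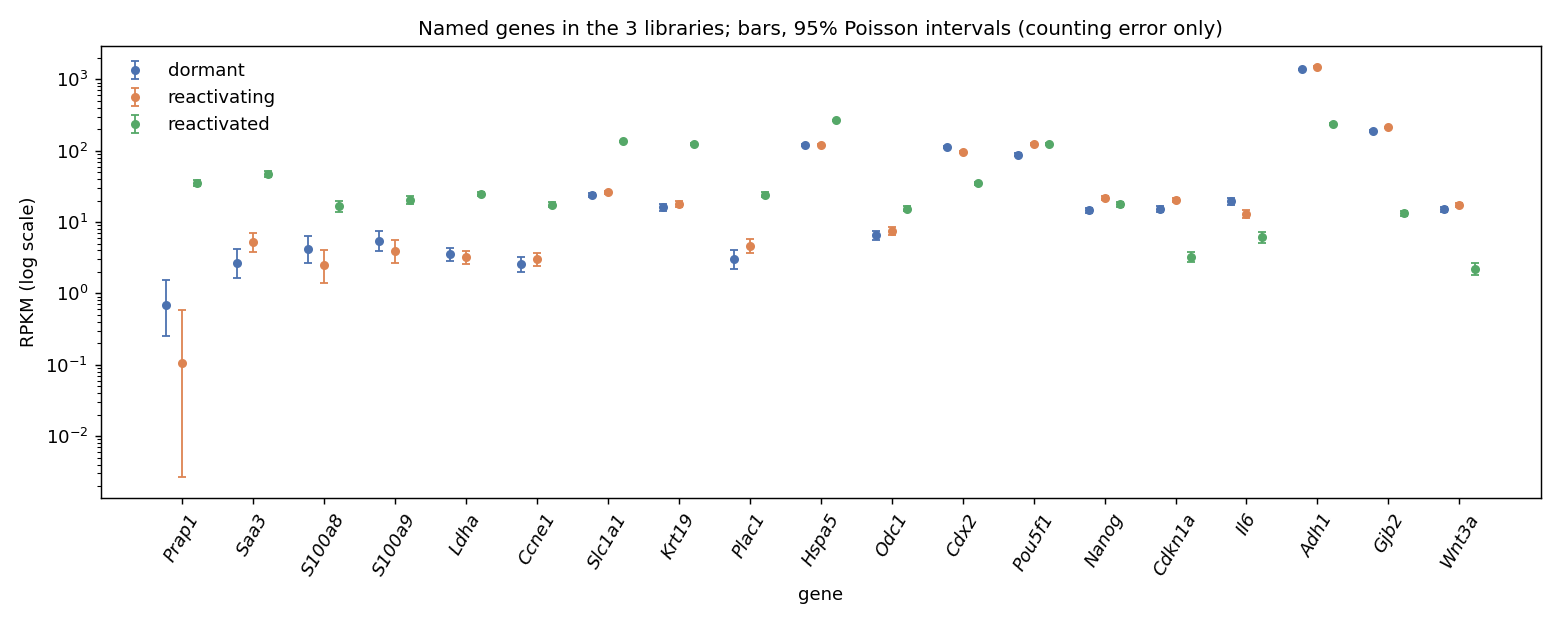
RPKM on a log scale (vertical axis) of named genes (horizontal axis) in the dormant, reactivating and reactivated libraries, 1 library each; bars are 95% Poisson intervals and cover counting error only. The genes shown are a selection of the named genes that leaves out those with large changes at 6 h, such as Myl12b and Sec31b. Within this selection most genes have close values in dormant and reactivating blastocysts and move in reactivated ones. Examples are Gjb2 at 190.1, 213 and 13.2 RPKM and Ldha at 3.55, 3.20 and 24.6 RPKM. The selection does not show how named genes in general behave.

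The third comparison set the reactivated against the reactivating library, the interval from 6 h to 12 h. Glycolysis genes were again higher (7 of 20 rose, median 0.85), as were genes of cholesterol synthesis (6 of 22, median 0.52), G1/S (8 of 40, median 0.57) and chaperones (5 of 39, median 0.55), all at percentile 100. Ldha rose by 2.61 on the log2 scale, Pkm by 2.02, Slc2a1, the main glucose importer, by 1.03 (0.997 with CPM, just under the rule) and Ccne1 by 2.20. Cell cycle inhibitors stood below the random lists here (6 of 27 fell and 2 rose, median -0.48, percentile 0.210), with Cdkn1a going from 20.3 RPKM (18.9 to 21.9) to 3.27. Of 46 genes of autophagy and lysosomes 13 fell (median -0.49) and of 23 immediate early genes 8 fell (median -0.85), both at percentile 0.0. Fatty acid oxidation had a median of -0.53 (percentile 0.180), where Cpt1a fell by 1.44 and Acadm fell by 1.15.

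Cytosolic ribosomal proteins were lower as a list (median -0.28, percentile 1.09, 2 of 77 fell), but at percentile 7.82 with CPM and at 5.14 with matching on GC content. Fatty acid synthesis was higher (median 0.26, percentile 98.4, Fads2 rising from 0.200 to 3.84 RPKM), but at 95.5 at a minimum of 5 RPKM. The polyamine list had a median of 0.31 (percentile 98.7) and a mean of -0.01, with no gene rising and Arg1 and Sat2 falling, and was at percentile 89.0 with CPM. Proteasome (median 0.44), G2/M (0.36), ribosome biogenesis (0.43), translation (0.29), mitochondrial ribosomal protein (0.17) and histone (0.23) genes also stood above the random lists. Prap1 went from 1 read to 408 (0.10 to 35.4 RPKM), and Slc40a1, Dmkn and Saa3 rose by 3.57, 3.37 and 2.94 on the log2 scale. Gjb2 fell by 3.91, Arl14 fell by 3.79, Acss1, an acetyl-CoA synthetase of mitochondria, fell by 2.86, and Wnt3a fell by 2.52. Of the 20 inflammatory genes S100a8, S100a9 and Saa3 rose and 5 fell, among them Icam1, an adhesion receptor, from 10.4 to 3.25 RPKM (list median -0.24, mean 0.02, percentile 27.9).

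Here 461 genes were higher and 920 lower among 12065 tested, with 243 higher and 659 lower among protein-coding genes. The median of all tested genes was -0.13, and -0.01 after median-ratio scaling, so that the balance of directions depended on the scaling: 33.4% of the changed genes were higher, 47.0% with median-ratio scaling and 44.0% with upper-quartile scaling (protein-coding genes 26.9%, 41.5% and 38.3%). No list that stood apart changed sign under these scalings, and 14 of the 17 kept their place in all 10 alternatives. Among autosomal protein-coding genes, the median log2 difference fell with GC content here too. It went from 0.12 in the fifth with the lowest GC content to -0.37 in the fifth with the highest. Scaling each library by a single factor does not take such a trend away.

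The X chromosome was compared with the autosomes because X dosage was a question set before the data were examined. At 6 h, the median log2 difference of X-linked genes from dormant minus that of autosomal genes was -0.02, within the random range (percentile 27.7 of expression-matched autosomal sets, 534 X-linked and 11884 autosomal genes). It lay below the range among protein-coding genes (-0.05, percentile 1.03). The same held without predicted genes, a set that leaves out genes with Rik names too (-0.04, percentile 2.37). At 12 h the X-linked median was 0.11 and the autosomal one -0.08, a difference of 0.19 (percentile 100 of the 10000 sets), which was 0.11 (percentile 99.0) at a minimum of 5 RPKM. It was 0.15 among protein-coding genes and 0.15 without predicted genes, both at percentile 100. The difference between 12 h and 6 h was 0.17 (percentile 100). Measured from the median of the random sets, the X was 0.21 higher at 12 h than in dormant blastocysts with sets matched on expression, and 0.12 higher (percentile 99.99) with sets matched also on exon length and GC content. Reads in introns (229 X-linked genes) gave -0.00319 at 12 h against dormant (percentile 32.7), -0.10 at 6 h (percentile 0.0300) and 0.15 between 6 h and 12 h (percentile 99.88). The ratio of the median X-linked to the median autosomal RPKM was 0.522 in dormant, 0.517 in reactivating and 0.617 in reactivated blastocysts, and 0.655, 0.639 and 0.718 among protein-coding genes, whose X-linked median was 4.51, 4.62 and 4.58 RPKM. Their autosomal median was 6.89, 7.23 and 6.38 RPKM. From dormant to reactivated the protein-coding ratio thus rose mainly because the autosomal median fell. By the size rule 39 X-linked genes were higher and 30 lower at 12 h than in dormant blastocysts, but 12 and 18 among protein-coding genes, 19 and 22 without predicted genes, 30 and 36 with CPM and 16 and 18 at a minimum of 5 RPKM.

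Single X-linked genes that rose included Plac1. Sat1, a polyamine acetyltransferase, was at 7.53 and 13.9 RPKM, below the rule. Rlim, a ubiquitin ligase that promotes X inactivation, was listed at 39.6 RPKM in dormant and 40.3 in reactivating blastocysts. Its reactivated value of 73.0 RPKM did not follow from its 7486 reads, which gave 53.0 RPKM, and neither value passed the rule. Spen, a repressor that acts in X inactivation, fell from 7.33 to 2.62 RPKM. The 7 measured genes known to escape X inactivation had a median of -0.15 and none passed. Xist and Tsix were not analysed here.

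**Figure D3:**
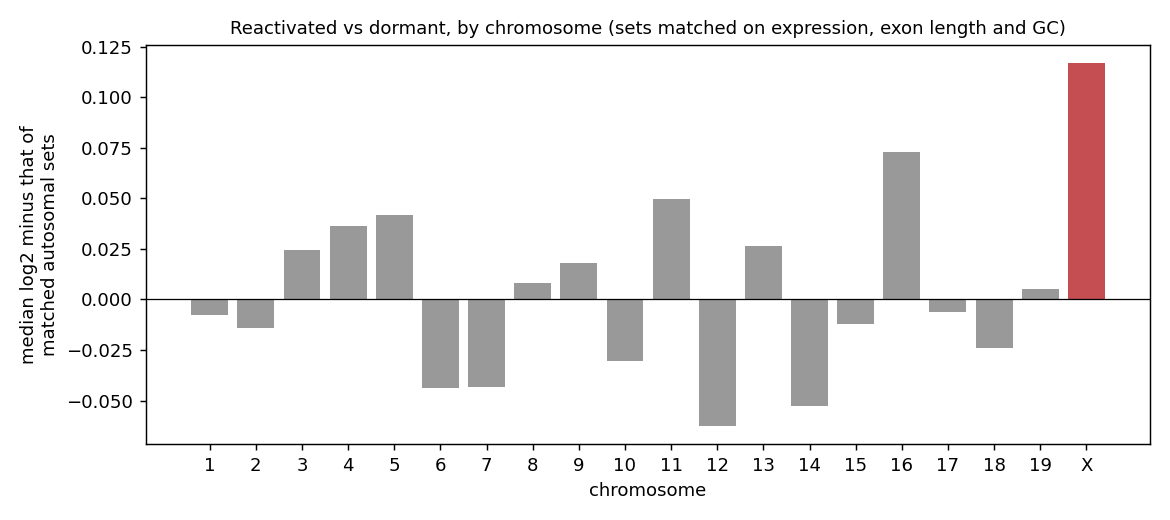
Median log2 difference between reactivated and dormant blastocysts of the genes of each chromosome (horizontal axis) minus that of autosomal sets matched on expression, exon length and GC content (vertical axis, log2 units), with the X chromosome in red. The X lies at 0.12 and the farthest autosome, chromosome 16, at 0.07.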

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

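Reads on the strand opposite to the annotated gene, which no comparison used, were more frequent in both E2-treated states than in dormant blastocysts, and this excess over the dormant library drew attention to them. Outside small RNA and mitochondrial genes they made up 5.04% of reads in the dormant library (95% Wilson interval 5.03 to 5.06%), 6.11% in the reactivating library (6.10 to 6.13%) and 6.71% in the reactivated library (6.70 to 6.72%). No explanation was tested, and 1 library per state leaves the preparation of the libraries and the state of the embryos tied together.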

How the results depend on the processing

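No paired analysis was possible because each state had 1 library, and leaving out a replicate was not possible for the same reason. Values with CPM, with protein-coding genes or genes outside the small RNA classes, with matching on exon length or GC content, and with intron reads come from alternatives chosen after seeing the data. Of the results with a called direction, the X chromosome minus the autosomes at 12 h against dormant changed sign with intron reads (-0.00319), and no other did under the alternatives run. Median-ratio scaling kept every count within 1.5 times the reported one and every list and the X chromosome on their side of the random range. Upper-quartile scaling did the same except for housekeeping genes at 6 h. Leaving out the minimum could change no count of higher or lower genes. A log2 difference of 1 on RPKM + 1 already needs at least 1 RPKM in the higher library. Of 257 calls of named genes, 6 fell under the size rule with median-ratio scaling, 3 with upper-quartile scaling, 3 with the reduced total and 3 with CPM. With a pseudocount of 0.1 the number was 0, which is no check, since a smaller pseudocount can only widen a difference. For the values that moved, below, the cause was not tested, apart from what follows from the rule itself. A higher minimum or fewer gene classes leave fewer genes to count, and a pseudocount of 0.1 can only raise the counts. With CPM, the added 1 weighs less than 1 RPKM for genes over 1 kb, so that more low genes of that length can pass. How much of the change with CPM this makes up was not measured.

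Counts are given as higher and lower genes. With a pseudocount of 0.1 they were 617 and 598 for reactivating against dormant (6 h), 959 and 1630 for reactivated against dormant (12 h) and 756 and 1618 for reactivated against reactivating. With a minimum of 5 RPKM they were 131 and 185 at 6 h and 290.0 and 610.0 between 6 h and 12 h. The reduced total, without mitochondrial, small RNA and histone genes, gave 163 and 125 at 6 h. With CPM the lower genes numbered 227 at 6 h, 1388 at 12 h and 1462 between them. Intervals that do not overlap left 183 and 198 at 6 h. Outside the small RNA classes there were 198 and 118 at 6 h and 305 higher genes between 6 h and 12 h. Among protein-coding genes there were 68 and 29 at 6 h, 361 and 550.0 at 12 h and 243 higher genes between them. At 5 RPKM 7025, 7146 and 6628 genes were detected in the 3 states, and at 0.1 RPKM 17695 in the reactivated one.

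For lists, the values are percentiles among random lists. With a pseudocount of 0.1, immune markers lay at 2.46 at 6 h and 1.82 between 6 h and 12 h, and cell cycle inhibition at 0.71 at 12 h. With a minimum of 5 RPKM, naive epiblast markers lay at 0.0 at 12 h, inflammatory genes at 99.99 at 12 h and 99.99 between 6 h and 12 h, interferon response at 1.91 and cell cycle inhibition at 1.61 at 12 h, histones at 97.1 at 6 h and 95.3 at 12 h, cytosolic ribosomal proteins at 99.97, mTOR at 7.42, Myc partners at 1.18, apoptosis at 84.6 and housekeeping genes at 1.31 at 6 h, and fatty acid synthesis at 95.5 between 6 h and 12 h. With the reduced total, trophectoderm lay at 0.69, primitive endoderm at 1.59, translation at 1.20 and housekeeping genes at 0.35 at 6 h, translation at 96.8 at 12 h, and formative epiblast at 97.8, immune markers at 2.27 and mitochondrially encoded proteins at 98.1 between 6 h and 12 h. With upper-quartile scaling, housekeeping genes lay at 2.33 at 6 h.

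With CPM, uterine epithelium lay at 0.78, uterine stroma at 1.48, histones at 94.3, proteasome at 99.75 and prostaglandin genes at 2.03 at 6 h. At 12 h, stroma lay at 1.57, cell cycle inhibition at 0.825, nuclear oxidative phosphorylation at 99.73 and fatty acid oxidation at 3.39. Between 6 h and 12 h, formative epiblast lay at 98.2, stroma at 0.93, immune markers at 1.77, cytosolic ribosomal proteins at 7.82 and polyamine genes at 89.0. With a protein-coding background, trophectoderm lay at 0.85, primitive endoderm at 1.46, uterine epithelium at 2.29, immune markers at 1.41, translation at 1.33 and housekeeping genes at 0.59 at 6 h, translation at 97.2 at 12 h, and formative epiblast at 98.0, immune markers at 1.76 and mitochondrially encoded proteins at 98.5 between 6 h and 12 h.

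With matching on exon length, trophectoderm lay at 0.82, stroma at 1.92, histones at 92.0, translation at 1.39 and housekeeping genes at 0.58 at 6 h, translation at 97.3 and fatty acid synthesis at 98.4 at 12 h, and trophectoderm at 2.05 and formative epiblast at 98.8 between 6 h and 12 h. Without matching, immune markers lay at 1.46, proteasome at 97.7 and immediate early genes at 3.52 at 6 h, trophectoderm at 3.41, nuclear oxidative phosphorylation at 99.95 and fatty acid oxidation at 4.20 at 12 h, and formative epiblast at 97.8, immune markers at 2.38 and mitochondrially encoded proteins at 99.2 between 6 h and 12 h. With matching on GC content, housekeeping genes lay at 2.45 at 6 h, trophectoderm at 2.64, formative epiblast at 97.7, translation at 97.0, nuclear oxidative phosphorylation at 98.9 and fatty acid oxidation at 3.01 at 12 h, and formative epiblast at 99.2, cytosolic ribosomal proteins at 5.14 and adhesion genes at 99.2 between 6 h and 12 h.

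The X chromosome minus the autosomes at 6 h left the random range downwards among protein-coding genes (-0.0479), without predicted genes (-0.0419) and in intron reads (-0.10), and at 12 h intron reads gave -0.00319, inside it. Counting depth limited mainly short genes, since with 3 reads a gene with 1 kb of exon reaches 0.212 RPKM in the dormant library.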

Other observations

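The tests of differences between chromosomes in general, of Y-linked genes, of the recovery of short transcripts, and of maternal immune cells and uterine epithelium, including their bounds, were chosen only after the result was seen. The same holds for the rules that leave tests open. Markers near the detection limit leave the uterine test open and, with the high level of Laptm5, the immune test. A trend with exon length leaves the test of short transcripts open, and junction reads in few of the genes leave the test of spliced mRNA open.

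Oxidative phosphorylation and the TCA cycle did not stand apart as lists at 12 h against dormant. Of 82 measured nuclear genes of oxidative phosphorylation, 3 rose and 4 fell against dormant (median 0.18, percentile 95.4, but 99.73 with CPM, 99.95 without matching and 98.9 with matching on GC content), with Ndufa12 rising by 1.46 on the log2 scale and Cox7a1 falling, and none of 20 genes of the TCA cycle passed the size rule (median 0.19, percentile 70.4). Of 15 genes of fatty acid synthesis, Fads2, a desaturase, rose. Among 39 entries of the chromatin list (38 genes, with Tet1 in the tables under 2 IDs) Uhrf1, the partner of the maintenance DNA methyltransferase, rose from 8.31 to 20.75 RPKM, while Tet2 and Kmt2a fell and the median was 0.03. Id1, a target of BMP signalling, was the single gene of 23 in the TGF-beta, BMP and Nodal list that rose. Of 11 Myc family genes Mxd4, an antagonist of Myc, fell, while Mycn stood at 42.1, 43.9 and 47.5 RPKM and Myc at 14.2, 11.3 and 15.3 RPKM in dormant, reactivating and reactivated blastocysts.

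Imprinted genes held few that moved. Of 11 paternally expressed ones Peg3 fell from 11.9 RPKM in dormant to 3.88 in reactivated blastocysts and Impact from 30.02 to 14.2, and of 14 maternally expressed ones Igf2r fell (list medians -0.09 and -0.02, both within the random range). Of 22 apoptosis genes Pmaip1 and Birc5 rose and none fell (median -0.09), and of 32 genes of mTOR and growth the insulin receptor gene Insr, Igf2r and Rps6 fell (median -0.26, percentile 5.84). Rps6 has many pseudogenes and is uncertain. Of 13 genes of prostaglandin, endocannabinoid and steroid signalling Ptges and Rxrb fell. None of 11 markers of trophoblast giant cells and none of 7 of the formative epiblast passed against dormant, with medians of 0.15 and 0.38. Of 24 housekeeping genes Pgk1 rose and Polr2a fell, with a median of 0.11 inside the random range.

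Intron reads, which come mostly from RNA not yet spliced, gave a view of when the 12 h changes began. For 273 genes higher in reactivated than in dormant blastocysts, the median log2 intron ratio at 6 h differed from that of unchanged genes matched on intron reads by -0.0112, while at 12 h it lay 0.75 above them. For 428 genes lower at 12 h the same difference was 0.0419 at 6 h and -0.83 at 12 h. Both intron values at 6 h argue against the hypothesis that transcription of these genes had already turned by 6 h. The exon values of the higher genes do not go with this, as their median at 6 h was already 0.28, and that of the lower genes -0.01. Choosing genes against the same dormant library can raise that median without any change. With the genes chosen on a random part of the dormant reads and measured on the rest, the median over 20 such splits was on average 0.25 for higher genes and 0.07 for genes neither higher nor lower, a check chosen after the value was seen that removes shared counting error but no other error of that library. Each time point was 1 library, and a change in the stability of mRNA or of introns was not tested.

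The first pattern weighed is the shift of X-linked genes at 12 h. GC content and exon length went with part of it. With sets matched on both, the distance of the X median from the sets shrank from 0.21 to 0.12, at percentile 99.99. This matching had its number of bins set to 5, so that differences in GC content or exon length within a bin could remain. The test therefore cannot tell whether these properties explain the rest of the shift. Differences between chromosomes in general reached 0.0731 (chromosome 16) with the same matching, less than the X. A lower share of male embryos in the reactivated pool cannot be told apart, because the median log2 ratio of 4 Y-linked genes was -0.0485 while single genes went from -0.57 for Kdm5d to 0.75 for Eif2s3y. Intron reads do not all point one way, with the X at -0.10 at 6 h, at -0.00319 at 12 h against dormant and at 0.15 between 6 h and 12 h. A change in X dosage with reactivation may underlie the shift, as a hypothesis that 1 pool per state leaves open.

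The second pattern is that genes changed at 6 h were short. Counting error as the whole cause is argued against by the 67.7% of changed genes outside the small RNA classes whose intervals did not overlap. A difference in the recovery of short transcripts cannot be told apart: the 272 changed genes under 1 kb went both ways (167 higher and 105 lower, 61.4% in the commoner direction), but over autosomal protein-coding genes the median log2 difference went from 0.14 in the fifth with the shortest exons to -0.01 in the fifth with the longest. Reads that do not come from spliced mRNA cannot be told apart either, because the median log2 ratio of 1.62 in junction reads covers 26 of the 198 higher genes, and the 172 with too few junction reads are those the explanation would concern. A difference between libraries that acts on single short transcripts in either direction has no test here, and neither has a biological explanation beyond the E2 treatment itself, so that the pattern may be technical or biological.

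The third pattern is the rise of S100a8, S100a9 and Saa3 at 12 h. Maternal immune cells cannot be told apart as a source by the 5 measured markers (Laptm5, Cd14, Cd68, Tyrobp and H2-Ab1). All 5 were lower in reactivated than in dormant blastocysts (median -1.09, from -1.53 to -0.52). Their fall does not exclude cells that lack these markers. Tyrobp (9 reads in dormant, 0 in reactivated) and H2-Ab1 (19 and 11 reads) were near the detection limit. Laptm5 stood at 13.7 RPKM in dormant blastocysts, where Ptprc of the same list was at 0.09. The fall of Laptm5 need therefore not reflect immune cells. Markers under 1 RPKM went both ways on few reads from dormant to reactivated blastocysts. Ptprc (0.09 to 0.2 RPKM), Cx3cr1 (0.0 to 0.14), Fcer1g (0.47 to 0.78) and Cd3e (0.05 to 0.11) rose. Lyz2 (0.72 to 0.04), Cd74 (0.9 to 0.48), Coro1a (0.42 to 0.11), Itgam (0.35 to 0.13) and C1qa (0.63 to 0.05) were among those that fell. Csf1r was at 0.54 in both, and Camp and Ngp had 0 reads in each library. Of 2 receptor genes of neutrophils looked up after these values were seen, Csf3r fell from 31.9 to 6.18 RPKM and Cxcr2 rose from 3.35 to 12.1 RPKM, so that the evidence does not all point one way. Maternal uterine epithelium cannot be told apart as a source: the ratio of its marker Ltf, reactivated over reactivating, was 1.03 (95% interval 0.668 to 1.62), but Ltf had 11 reads in dormant, 39 in reactivating and 49 in reactivated blastocysts, Areg had 4, 1 and 20 and Prss29 had 26, 3 and 19 in the same order, levels under 1 RPKM except Prss29 in dormant blastocysts (1.82 RPKM). A response of the embryo itself to E2 may be the source, which these libraries leave untested.

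The deposited RPKM of Rlim in the reactivated library, 73.0, differed from the 53.0 that its reads give, the single such case among 31510 genes in 3 libraries.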
